A study of Homo sapiens with 24 samples.

How the data were processed

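HepG2 cells were plated at 10000 cells per well and treated with 1 uM BRD8518, 100 ng/mL OSM or vehicle, with 0.25% DMSO in the medium, per the labels' protocols. RNA was purified with RNeasy kits, amplified with the Ambion WT Expression kit and labelled with the GeneChip WT terminal labelling kit for an Affymetrix whole-transcript array, per the same protocols. The labels put 24 arrays in 8 groups of treatment and time. The protocols shared by all samples mention 6 wells per treatment, but nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The labels also carry a position code of a letter and a number whose meaning they do not state. The shared protocol describes a dose series at 6 h as well, while the 6 h arrays are labelled 1 uM, and other doses are not analysed here.

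The deposited values are on a log2 scale and were made by the authors with RMA in the oligo package, per the submitters' processing notes, whose versions are not given in the sources used here. They ran from 0.913 to 13.7 for 53617 probe sets, with array medians from 4.89 to 4.95, and were used as deposited. RMA values carry no detection calls, so signal over background could not be judged probe set by probe set, and 2388 of the genes tested had a mean value under 4, where changes tend to be compressed. Arrays give no sequencing depth, and the number of arrays per group limits the precision of each change.

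Gene symbols came from the platform's annotation table. It named 1 symbol for 16098 probe sets and several for 0, and 37519 probe sets stayed unnamed here. All 16098 gene identifiers were found in the RefSeq gene table, and 0 symbols changed. For the 779 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, whatever the group, which left 14884 genes. No gene was left out for low signal. Of the 10 panel genes fixed, 6 were measured (TRIB1, TRIB2, TRIB3, APOB, MTTP and SOCS3), and the others are not reported here. A probe set named for a microRNA reads its precursor or the transcript around it, not the mature microRNA, and probe sets of near-identical genes may read each other. The genome build of the probe sets is not given in the sources used here.

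The 24 arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group, equal weights and empirical Bayes moderation without trend or robust options (prior degrees of freedom 5.3, total 21.3). Contrasts of group means gave 5 comparisons with time-matched DMSO, 2 of BRD8518 with OSM, and 4 of effects between times. P values are from moderated t tests on 2 sides, adjusted by Benjamini-Hochberg over the genes of each contrast, and genes with an adjusted p under 0.05 are said to have changed. Standard errors and 95% confidence intervals come from the same fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.

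Before the data were examined, 23 gene lists with 483 genes were fixed, of which 285 were measured. The 20 lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01 and adjusted by Benjamini-Hochberg over the lists of a contrast. The 3 others, the TRIB1 axis, tubulin genes and AhR and PXR/CAR targets, were not tested. A list's members were counted by the gene test, and again with that test adjusted over the list alone. Lists share members, so their results are not independent. The genes to name were also set by rule before the data were examined. In each comparison with DMSO they are the 10 largest rises and 10 largest falls past the threshold whose treated arrays all lay on 1 side of all control arrays, and in the other comparisons the 5 largest each way. Added to these are the panel and up to 4 members per direction of each list.

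Alternatives fixed before the data were examined were a filter on genes under the median level, centring each array on its median, quantile normalization, moderation with trend and robust options, a fit of the compared groups alone, array weights, the mean of a gene's probe sets, the position letter as a random block or a fixed term, and leaving out each array of the compared groups in turn. For lists they were an estimated correlation between genes and the rotation test fry. Letter C of the position code lay on BRD8518 1 h replicates 2 and 3 alone. As a fixed term it thus left replicate 1 to set that group's level. A fit without DMSO 6 h replicate 2 was added after that array was seen to stand apart. The correlation and covariance of changes against shared controls were set beside those of simulated unchanged groups with the same controls. Group labels at 1 h and 24 h were also split in every other way, or in 100 drawn ways for effects between 1 h and 24 h. Comparisons with 6 h arrays were not split, since BRD8518 had 2 arrays there.

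The fit was tested on simulated data with 50 genes changed per size among 14884. At a log2 change of 1 it recovered 98% of them for BRD8518 at 1 h, 98% at 6 h and 94% at 24 h, and 96% and 98% for OSM at 1 h and 24 h. At a log2 change of 0.5 it recovered 60%, 48% and 76% for BRD8518 at the 3 times and 68% and 58% for OSM, and false calls made up 3.26% to 7.53% of all calls in these 5 comparisons. For the effects between 1 h and 24 h it recovered 22% for BRD8518 and 28% for OSM at a log2 change of 0.5. A list raised by 0.5 was called by camera, with 0 of the 19 others. Simulated genes varied independently and with 1 spread over all arrays. Correlation within lists and the noisier DMSO array at 6 h were not simulated, so these rates may not hold for the data.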

Results

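Transcript levels were measured on 24 whole-transcript arrays of HepG2, a human liver carcinoma line that keeps many hepatocyte traits. The cells received BRD8518, a small molecule known here by its code name, at 1 uM, the cytokine oncostatin M (OSM) at 100 ng/mL, or the DMSO vehicle. BRD8518 was measured at 1 h (3 arrays), 6 h (2 arrays) and 24 h (3 arrays), OSM at 1 h (3) and 24 h (3), and DMSO at 1 h (3), 6 h (4) and 24 h (3). No OSM arrays at 6 h were analysed here. Levels are log2 values and changes are differences of group means on that scale, given with their standard error (SE) from the fit. Every gene named among the largest changes against DMSO had all treated arrays on 1 side of all control arrays. In the fit, 14884 genes entered, and the median SE of a change against DMSO was 0.11 to 0.12. Arrays carry no read depth, so their number limits the precision, and it was lowest for BRD8518 at 6 h.

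The series deals with compounds that induce TRIB1, which encodes the pseudokinase tribbles 1. Of the list built around it, 3 of 6 genes were measured (TRIB1, TRIB2 and TRIB3), too few for a list test, and 0 of 12 tubulin genes. TRIB1 stood at 9.13 ± 0.02 (SD, n = 3) in the 1 h DMSO arrays, 9.15 ± 0.13 (n = 4) at 6 h and 9.27 ± 0.09 (n = 3) at 24 h. Under OSM it was 10.81 ± 0.10 at 1 h and 9.84 ± 0.11 at 24 h (n = 3 each). With BRD8518 it was 9.33 ± 0.03 at 1 h (n = 3), 10.54 ± 0.10 at 6 h (n = 2) and 10.48 ± 0.05 at 24 h (n = 3).

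**Figure D1:**
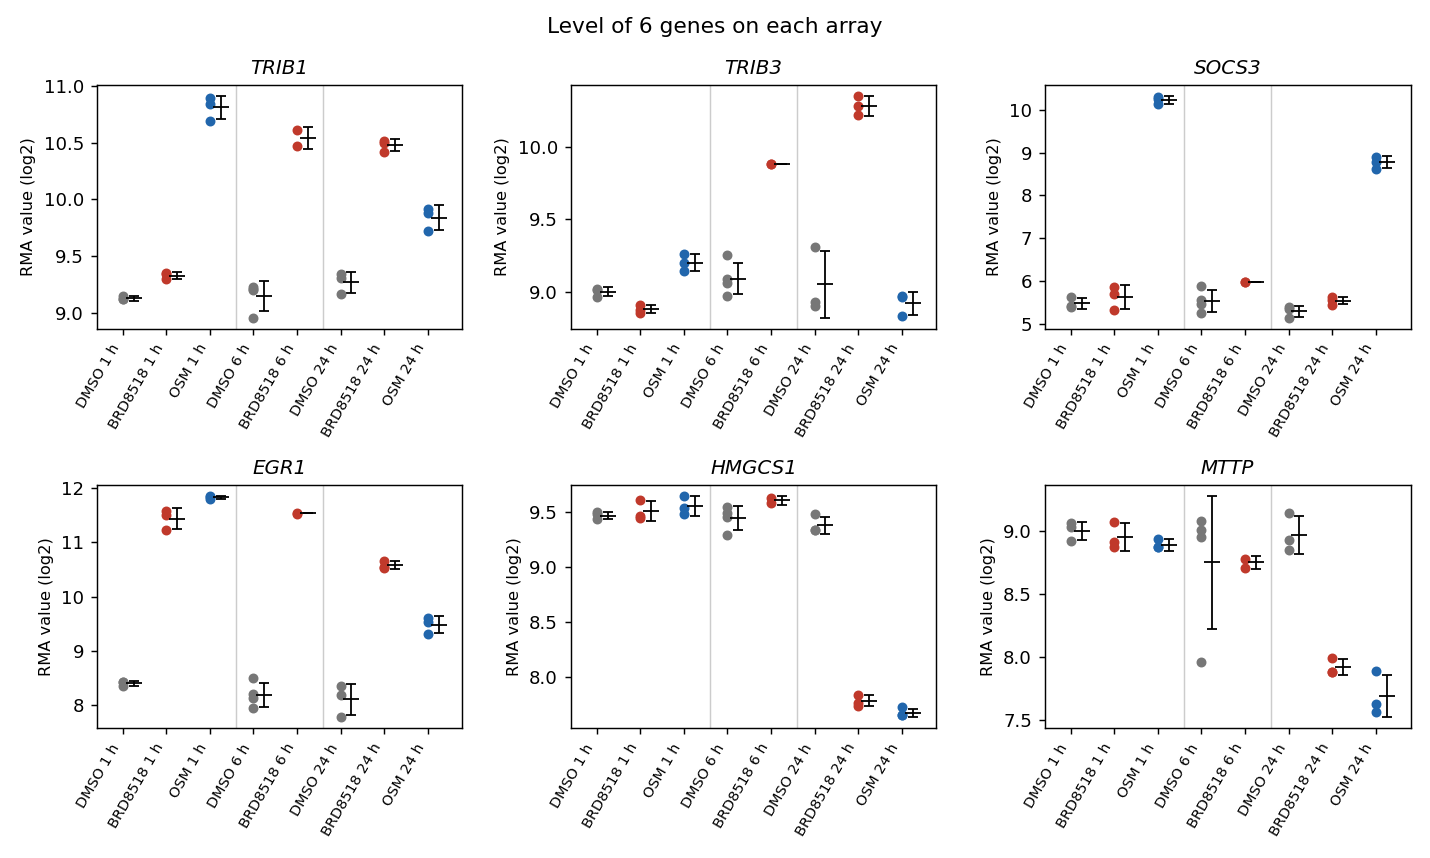
Level of TRIB1, TRIB3, SOCS3, EGR1, HMGCS1 and MTTP (RMA value, log2, vertical axes) in the 8 groups (horizontal axes, by time), where each point is 1 array and the bar beside it is the group mean ± SD. The OSM arrays at 1 h hold the highest TRIB1 values (mean 10.81), the BRD8518 arrays at 24 h hold the highest TRIB3 values (mean 10.28), and 1 of the 4 DMSO arrays at 6 h lies apart for MTTP (7.96).

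After 1 h of BRD8518, EGR1, a zinc-finger factor induced by growth signals, rose most, 8.22-fold, from 8.40 ± 0.05 to 11.44 ± 0.19 (SD, n = 3 each; log2 change 3.04 ± 0.13, limma, Benjamini-Hochberg adjusted p = 2.0e-12). The AP-1 subunits JUN, FOS and JUNB rose by 1.49 ± 0.08, 1.13 ± 0.16 and 1.09 ± 0.12, and the Krüppel-like factor KLF6 rose by 1.17 ± 0.09. ARRDC3, an arrestin-domain protein, rose by 1.78 ± 0.13 and TCIM by 1.23 ± 0.09. Probe sets for the microRNA precursors MIR3189, MIR554 and MIR21 rose by 1.65 ± 0.19, 1.53 ± 0.15 and 1.37 ± 0.14. They overlap GDF15, TUFT1 and VMP1, whose transcripts they may also catch. MIR17HG, the host transcript of the miR-17-92 cluster, fell by 0.94 on the log2 scale (SE 0.15), and the translation factor gene EIF5 fell by 0.75 (SE 0.13). TRIB1 differed by 0.20 ± 0.08 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.86), and neither did TRIB3 (−0.12 ± 0.09), SOCS3 (0.15 ± 0.14) or MTTP (−0.05 ± 0.18).

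In all, 38 genes passed at 1 h with BRD8518, 33 higher and 5 lower, and 11 of them changed at least 2-fold, all upward. At an unadjusted p under 0.05 there were 760 genes, where 744 would be expected by chance. The remaining 3 falls were small: MIR4521 (−0.75 ± 0.16), MIR15A (−0.60 ± 0.12, within DLEU2) and TARDBP (−0.44 ± 0.09). MIR4521 kept its call without BRD8518 replicate 2 and lost it without any other array (−0.76 to −0.63), as did MIR15A with BRD8518 replicate 1 as the exception (−0.62 to −0.53), and TARDBP lost it without any 1 of the 6 arrays (−0.46 to −0.39). The EIF5 call was lost without DMSO replicate 1 (−0.67) or replicate 2 (−0.66), and the FOS call with the mean of its probe sets (0.63). The count was 25 without BRD8518 replicate 2, 76 without the 6 h DMSO array that lay apart (55 higher and 21 lower) and 81 with array weights. With the letter of the arrays' position code as a term, replicate 1 alone set the BRD8518 level, so no count is given.

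Among the fixed gene lists, MAPK immediate-early and feedback genes moved furthest at 1 h of BRD8518. Of 29 measured, 11 rose, 0 fell and 18 did not pass (18 rose adjusted over the list alone), with a median change of 0.33 (camera, Benjamini-Hochberg adjusted p = 8.0e-50). JAK-STAT feedback and STAT3 targets held 4 rises in 21 (5 adjusted over the list alone), FOS, JUNB, BCL6 (0.77 ± 0.08) and MYC (0.43 ± 0.06), with a camera adjusted p of 1.3e-08. FOS, JUNB and MYC also belong to the MAPK list, so the call in part repeats that one. SRF/MRTF and YAP cytoskeletal targets held 2 rises in 12 (5 adjusted over the list alone; camera adjusted p = 4.2e-10). They were ANKRD1 (0.59 ± 0.09), which encodes a muscle and stress-induced ankyrin repeat protein, and the tropomyosin gene TPM1 (0.38 ± 0.08). The chemokine genes CXCL8 (0.79 ± 0.12) and CCL20 (0.58 ± 0.10) were the 2 that rose of 12 in the NF-kB and chemokine list (3 adjusted over the list alone; camera adjusted p = 1.0e-06). Of 11 p53 targets, GDF15, which encodes a stress-induced cytokine, rose by 0.58 ± 0.10 (1 adjusted over the list alone; camera adjusted p = 0.0083). DNA replication genes were lower as a list at a median of −0.08, with 0 of 21 past the threshold (1 lower adjusted over the list alone; camera adjusted p = 1.6e-05). Against the same DMSO arrays the median was −0.09 with OSM, and it was 0.01 between the treatments (camera adjusted p = 0.87). An effect of BRD8518 thus cannot be told apart from the level of the shared controls. CCL20 and GDF15 lost their calls without BRD8518 replicate 2 (0.49 and 0.53). TPM1 lost its call without any array but BRD8518 replicate 1 (0.33 to 0.41), when arrays were centred (0.36) and with the mean of its probe sets (0.27). CXCL8, CCL20, MYC and EIF5 did not pass in a fit of these 6 arrays alone. With the position letter as a term, replicate 1 alone set the BRD8518 level, so only changes are given. They were 0.43 for ANKRD1, 0.61 for CXCL8, 0.40 for CCL20, 0.49 for GDF15, 0.32 for MYC, 0.84 for FOS and −0.85 for EIF5. FOS did not pass with the mean of its probe sets (0.63), nor did EIF5 without DMSO replicate 1 (−0.67) or 2 (−0.66).

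Another 3 lists passed camera at 1 h of BRD8518 but not with an estimated correlation. List calls given without such a value, here and below, also passed with it. The list of positive acute phase proteins had a median of 0.10 with 0 rises in 17 (1 adjusted over the list alone; camera adjusted p = 0.0083, adjusted p = 0.14 with an estimated correlation). In the list of hepatocyte transcription factors and markers, the gluconeogenic enzyme gene PCK1 (0.63 ± 0.10) was the 1 rise in 15 (2 adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.14 with an estimated correlation). PCK1 did not pass in a fit of these 6 arrays alone. Its change was 0.56 with the position letter as a term, which rests on BRD8518 replicate 1 alone. Mitosis genes had a median of −0.05 with 0 falls in 22 (0 adjusted over the list alone; camera adjusted p = 0.0083, adjusted p = 0.43 with an estimated correlation). The other 11 lists had camera adjusted p values from 0.17 to 0.74, cholesterol synthesis and uptake (0 of 17 past the threshold, 0 adjusted over the list alone; median 0.03) among them. Of 12 markers of other cell types, SOX9 was 0.27 ± 0.06 higher (limma, Benjamini-Hochberg adjusted p = 0.043; 1 adjusted over the list alone), and it lost its call without any 1 of the 6 arrays (0.25 to 0.28).

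**Figure D2:**
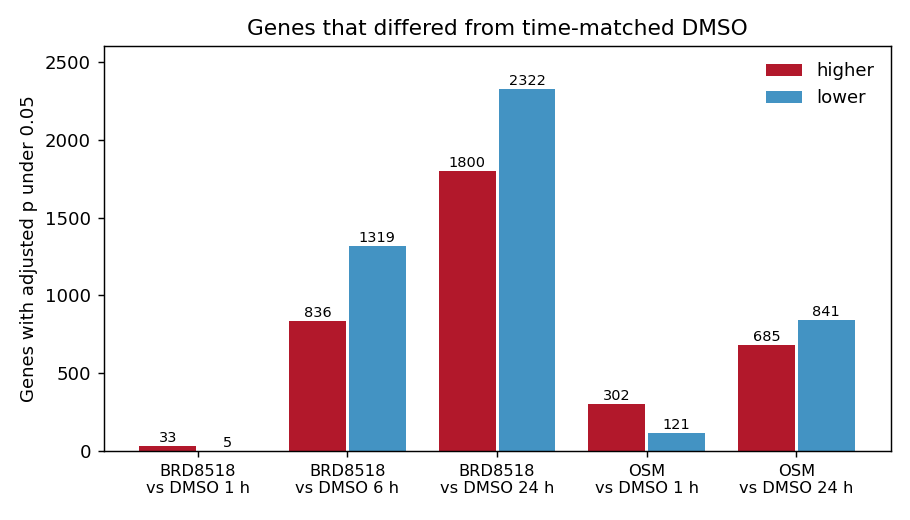
Number of genes (vertical axis) that were higher (red bars) or lower (blue bars) than time-matched DMSO at an adjusted p under 0.05, for the 5 comparisons with DMSO (horizontal axis). BRD8518 went from 33 higher and 5 lower at 1 h to 1800 higher and 2322 lower at 24 h, and OSM from 302 higher and 121 lower at 1 h to 685 higher and 841 lower at 24 h.

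At 6 h of BRD8518, TRIB1 was 2.62-fold higher than in DMSO (log2 change 1.39 ± 0.09, n = 2 and 4, limma, Benjamini-Hochberg adjusted p = 1.8e-10). TRIB3, a tribbles gene induced by amino acid and endoplasmic reticulum stress, rose by 0.78 ± 0.10, from 9.09 ± 0.11 (SD, n = 4) to 9.88 (n = 2). EGR1 was again at the top, 10.2-fold higher (3.34 ± 0.14), followed by EDN1, which encodes the vasoconstrictor endothelin 1 (7.81-fold, 2.97 ± 0.13), and RGCC, a regulator of the cell cycle (7.26-fold, 2.86 ± 0.15). ANKRD1 rose by 2.54 ± 0.10, the chemokine gene CCL20 by 2.23 ± 0.10, the kinase gene PLK3 by 2.20 ± 0.09, the cytokine gene IL11 by 2.15 ± 0.16, the non-coding LINC-PINT by 2.20 ± 0.17 and the keratin-associated KRTAP2-3 by 2.80 ± 0.23. The falls were smaller. FAM200C fell by 1.92 on the log2 scale (SE 0.21), the acetyltransferase gene KAT14 by 1.53 (SE 0.12), and the lipid droplet gene HILPDA by 1.48 (SE 0.11). RBBP6, which encodes an RB-binding ubiquitin ligase, fell by 1.31 (SE 0.14), FIGNL1 by 1.34 (SE 0.20) and CCDC18 by 1.40 (SE 0.19). The zinc-finger genes ZNF563 and ZNF221 changed by −1.50 ± 0.23 and −1.38 ± 0.24. MTTP (−0.00 ± 0.20; −0.27 without DMSO replicate 2, adjusted p = 0.051), APOB (−0.06 ± 0.07) and TRIB2 (−0.12 ± 0.12) did not pass, and SOCS3 was 0.45 ± 0.14 higher (limma, Benjamini-Hochberg adjusted p = 0.036).

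At 6 h, 2155 genes passed (14.5% of those tested), 836 higher and 1319 lower, with 101 at least 2-fold higher and 70 at least 2-fold lower. With each array centred on its median the split was 1309 higher and 943 lower, so the balance of rises and falls is not settled at 6 h. The count was 1349 without BRD8518 replicate 1, 1208 without BRD8518 replicate 2, 3345 without DMSO replicate 2, 3466 with array weights, and 452 in a fit of these 6 arrays alone. In that last fit ZNF563 and ZNF221 did not pass. The SOCS3 call was lost without either BRD8518 array (0.45 each) and without DMSO replicate 1 (0.46), replicate 3 (0.36) or replicate 4 (0.43), with the mean of its probe sets (0.33), and in the fit of these arrays alone. SNAR-H, a small non-coding RNA of a near-identical family, was 1.47 lower (−1.47 ± 0.45), but 0.88 lower without DMSO replicate 2, which held 9.73 against 7.04 to 7.56 in the other DMSO arrays, and did not pass without BRD8518 replicate 1 (−1.31) or replicate 2 (−1.62), or in the fit of these arrays alone. The remaining named fall was the precursor probe set MIR570 (−1.60 ± 0.22), which overlaps MIR570HG. KAT14, CCDC18, ZNF563 and HILPDA overlap PET117, TMED5, ZNF442 and EFCAB3P1 in the genome, whose transcripts may add to their values.

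MAPK immediate-early and feedback genes rose at 6 h of BRD8518 in 22 of 29 cases, with 0 falls and 7 that did not pass (22 adjusted over the list alone; median 0.91, camera, Benjamini-Hochberg adjusted p = 1.2e-33). They included the MAP kinase phosphatase genes DUSP5 (2.11 ± 0.13) and DUSP1 (2.10 ± 0.08), and JUN (1.98 ± 0.08). All 12 measured SRF/MRTF and YAP cytoskeletal targets rose (12 adjusted over the list alone; median 0.90, camera adjusted p = 7.4e-22), such as the actin-binding TAGLN (1.86 ± 0.12), SRF itself (1.08 ± 0.08) and the matricellular CCN2 (0.93 ± 0.08). In the JAK-STAT feedback and STAT3 list of 21, 11 rose, 2 fell and 8 did not pass (15 rose and 2 fell adjusted over the list alone; camera adjusted p = 3.5e-09). PIM1 (1.83 ± 0.13), JUNB (1.82 ± 0.13), the survival gene MCL1 (1.37 ± 0.14) and MYC (1.10 ± 0.07) rose, while the feedback inhibitor SOCS1 (−1.28 ± 0.14) and IRF1 (−0.48 ± 0.12) fell. CXCL8 (4.01-fold higher, SE 0.13 on the log2 scale) and the adhesion molecule gene ICAM1 (0.52 ± 0.08) were, with CCL20 and IRAK2, the 4 NF-kB and chemokine genes of 12 that rose (7 adjusted over the list alone; camera adjusted p = 1.6e-06). Of 11 p53 targets, PLK3, GDF15 (1.45 ± 0.10) and PLK2 (0.74 ± 0.11) rose (3 adjusted over the list alone; camera adjusted p = 0.0044), and the list had a median of 0.06 beside a mean of 0.40. IRF1 did not pass without BRD8518 replicate 2 (−0.41) or in a fit of these 6 arrays alone, and IRAK2 (0.29 ± 0.09) kept its call only without DMSO replicate 2 among the fits with 1 of these 6 arrays left out (0.26 to 0.30 in the others).

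Stress genes split at 6 h of BRD8518. DDIT3 (1.61 ± 0.11) and ATF3 (1.18 ± 0.15), transcription factors of the integrated stress response, and SESN2 (0.81 ± 0.09) were among 5 of 16 measured genes of that list that rose. The endoplasmic reticulum genes SDF2L1 (−0.58 ± 0.15) and CRELD2 (−0.52 ± 0.17) fell (5 rises and 2 falls adjusted over the list alone). The list's call (camera, Benjamini-Hochberg adjusted p = 0.0052) was lost at adjusted p = 0.17 with an estimated correlation. SRXN1 (1.29 ± 0.10), TXNRD1 (0.80 ± 0.08) and OSGIN1 (0.77 ± 0.12) rose among 7 NRF2 targets while HMOX1, the heme oxygenase gene, fell (−0.66 ± 0.08). That list had 3 rises and 1 fall adjusted over the list alone, and a camera adjusted p of 0.0089 (adjusted p = 0.088 with an estimated correlation). SDF2L1 did not pass without BRD8518 replicate 2 (−0.46). CRELD2 did not pass without BRD8518 replicate 1 (−0.62), BRD8518 replicate 2 (−0.42) or DMSO replicate 4 (−0.55), under centring (−0.44), quantile normalization (−0.50) or the position term. Neither gene passed in a fit of these 6 arrays alone, and OSGIN1 did not either.

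Lower lists at 6 h of BRD8518 covered cell division and lipid synthesis. DNA replication genes fell in 14 of 21 cases with 0 rises (16 adjusted over the list alone; median −0.41, camera, Benjamini-Hochberg adjusted p = 1.2e-11), for example the flap endonuclease gene FEN1 (−1.10 ± 0.11), the cyclin gene CCNE2 (−0.82 ± 0.15) and the origin licensing factor CDC6 (−0.71 ± 0.08). Mitosis genes fell in 10 of 22 cases (11 adjusted over the list alone; camera adjusted p = 3.3e-07), a call lost at adjusted p = 0.096 with an estimated correlation. Examples were the spindle kinesin KIF11 (−0.68 ± 0.11) and the kinase AURKA (−0.61 ± 0.10). Of 17 cholesterol synthesis and uptake genes, 8 fell and 0 rose (9 adjusted over the list alone; median −0.33, camera adjusted p = 6.2e-05), among them IDI1 (−0.82 ± 0.09), MVK (−0.70 ± 0.11), FDPS (−0.72 ± 0.12) and HSD17B7 (−1.16 ± 0.25). PNPLA3 (−0.68 ± 0.10), ACACB (−0.54 ± 0.08) and MLXIPL (−0.46 ± 0.12) were the 3 falls among 19 fatty acid and triglyceride synthesis genes (4 adjusted over the list alone; camera adjusted p = 0.0044). Lipoprotein secretion and remodelling genes fell in 4 of 19 cases (5 adjusted over the list alone; camera adjusted p = 0.036, adjusted p = 0.2 with an estimated correlation), with LCAT, the plasma cholesterol-esterifying enzyme, at −0.49 ± 0.11. MLXIPL did not pass without BRD8518 replicate 1 (−0.44) or replicate 2 (−0.47). In a fit of these 6 arrays alone MLXIPL, CCNE2, KIF11, AURKA, FDPS, HSD17B7 and LCAT did not pass.

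The other 8 lists did not pass camera at 6 h of BRD8518 (adjusted p from 0.076 to 0.6). Within them, the iron hormone gene HAMP (1.04 ± 0.20) was the 1 rise among 17 positive acute phase proteins (1 adjusted over the list alone). Higher members of other lists included the bile acid conjugating BAAT (0.78 ± 0.12), the tyrosine aminotransferase TAT (0.76 ± 0.15), PCK1 (0.53 ± 0.11) and, among 12 markers of other cell types, the macrophage-associated CD68 (0.51 ± 0.08; 1 adjusted over the list alone). The hepatocyte factor FOXA1 was lower (−0.35 ± 0.07). The bile acid list of 6 had a median of −0.08 beside a mean of 0.07 and an upward test direction (1 rise, and 2 rises and 1 fall adjusted over the list alone; camera adjusted p = 0.54). Negative acute phase proteins and hypoxia targets had medians of −0.07 and −0.06, and both medians were 0.01 when arrays were centred. In a fit of these 6 arrays alone HAMP, BAAT, TAT, PCK1, CD68 and FOXA1 did not pass.

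By 24 h of BRD8518, the 10 largest rises ran from 8.58-fold to 22-fold. LAIR2, which encodes a soluble collagen-binding immune receptor, rose from 2.84 ± 0.33 to 7.31 ± 0.15 (SD, n = 3 each; 4.46 ± 0.23, limma, Benjamini-Hochberg adjusted p = 1.3e-12). Its DMSO level, like that of TMEM156 (3.49), is low for this array, so the size of the fold is uncertain. RGCC rose 17.5-fold (4.13 ± 0.14), DUSP5, a phosphatase of ERK, 15.9-fold (3.99 ± 0.13), TMC7 12.2-fold (3.60 ± 0.14) and the receptor tyrosine kinase AXL 10.7-fold (3.42 ± 0.10). GPAT3, an enzyme of glycerolipid synthesis, rose by 3.21 ± 0.10, IL11 by 3.16 ± 0.15, TMEM156 by 3.22 ± 0.13 and TCP11L2 by 3.10 ± 0.11. The pseudogene probe set AQP7P3 rose by 3.36 ± 0.16, which near-identical aquaporin 7 copies may share. MAP2K6, a kinase upstream of p38, fell 7.44-fold (−2.89 ± 0.17). HOXD1 (−2.41 ± 0.15), the erythropoietin gene EPO (−2.36 ± 0.11), the alcohol dehydrogenase ADH6 (−2.30 ± 0.24), SMLR1 (−2.27 ± 0.11), TMT1A (−2.39 ± 0.14) and the sulfotransferase CHST9 (−2.26 ± 0.22) fell too. So did ACAT2, an acetyl-CoA acetyltransferase of the sterol pathway (−2.22 ± 0.08), the hepatocyte factor ONECUT1 (−2.22 ± 0.14) and HPR (−2.32 ± 0.14), a close copy of HP. TRIB1 was 2.31-fold higher (1.21 ± 0.08) and TRIB3 2.35-fold higher (1.23 ± 0.09). MTTP, the lipid transfer protein needed to load lipid onto apolipoprotein B, fell from 8.97 ± 0.15 to 7.92 ± 0.06 (−1.06 ± 0.18, limma, Benjamini-Hochberg adjusted p = 1.0e-04), while APOB (−0.06 ± 0.07), SOCS3 (0.23 ± 0.14) and TRIB2 (−0.16 ± 0.11) did not pass. In total 4122 genes passed (27.7%), 1800 higher and 2322 lower, with 279 at least 2-fold higher and 240 at least 2-fold lower.

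Sterol synthesis genes were lower together at 24 h of BRD8518. Of 17 cholesterol synthesis and uptake genes, 14 fell, 0 rose and 3 did not pass (15 fell adjusted over the list alone; median −1.24, camera, Benjamini-Hochberg adjusted p = 9.4e-17). IDI1 (−1.85 ± 0.08), the sterol carrier STARD4 (−1.65 ± 0.15) and HMGCS1 (−1.61 ± 0.08), the enzyme that makes HMG-CoA, were among them. Fatty acid and triglyceride synthesis genes fell in 14 of 19 cases and rose in 2 (14 and 3 adjusted over the list alone; median −0.47, camera adjusted p = 1.1e-05). PNPLA3 (−2.14 ± 0.09), the carbohydrate-responsive factor MLXIPL (−1.06 ± 0.11) and DGAT1 (−0.98 ± 0.07) fell, and the phosphatidate phosphatases LPIN2 (0.67 ± 0.09) and LPIN1 (0.64 ± 0.08) rose. The lipoprotein list did not pass (camera adjusted p = 0.077), with 8 falls and 1 rise among 19 (8 and 2 adjusted over the list alone). Its falls included APOM (−1.25 ± 0.10), LCAT (−1.11 ± 0.10) and APOC3 (−1.09 ± 0.13), and its rise was the receptor gene VLDLR (1.79 ± 0.10).

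Cell division genes fell almost throughout at 24 h of BRD8518. DNA replication genes fell in 20 of 21 cases (21 adjusted over the list alone; median −1.09, camera, Benjamini-Hochberg adjusted p = 3.4e-24), such as CDC6 (−1.81 ± 0.08), FEN1 (−1.64 ± 0.10), UHRF1 (−1.63 ± 0.11) and GINS2 (−1.61 ± 0.12). All 22 measured mitosis genes fell (22 adjusted over the list alone; median −0.76, camera adjusted p = 2.4e-17), among them KIF11 (−1.29 ± 0.10), the survivin gene BIRC5 (−1.17 ± 0.10) and AURKB (−1.08 ± 0.09). MAPK immediate-early and feedback genes stayed higher in 18 of 29 cases with 0 falls (18 rises and 1 fall adjusted over the list alone; median 0.64, camera adjusted p = 9.5e-15), with EGR1 at 2.48 ± 0.13, DUSP1 at 1.90 ± 0.07 and DUSP8 at 1.80 ± 0.10. SRF/MRTF and YAP cytoskeletal targets rose in 10 of 12 cases (10 adjusted over the list alone; camera adjusted p = 5.3e-09), with ANKRD1 (2.23 ± 0.09), FHL2 (1.69 ± 0.11) and TAGLN (1.62 ± 0.11). JAK-STAT feedback and STAT3 targets rose in 10 and fell in 2 of 21 cases (10 and 2 adjusted over the list alone; camera adjusted p = 7.9e-05). The interleukin 6 receptor gene IL6R (2.24 ± 0.09), PIM1 (1.88 ± 0.12), TIMP1 (1.51 ± 0.16) and JAK2 (1.25 ± 0.15) rose and SOCS1 (−1.63 ± 0.13) fell.

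Liver-secreted proteins and hepatocyte factors tended downward at 24 h of BRD8518. Positive acute phase proteins fell in 7 of 17 cases and rose in 0 (7 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.013, adjusted p = 0.14 with an estimated correlation), with ceruloplasmin (CP, −1.13 ± 0.11), haptoglobin (HP, −0.80 ± 0.10) and hemopexin (HPX, −0.76 ± 0.10). Negative acute phase proteins fell in 4 of 9 cases (5 adjusted over the list alone; camera adjusted p = 0.0072, adjusted p = 0.094 with an estimated correlation), with APOM, transthyretin (TTR, −0.75 ± 0.07) and transferrin (TF, −0.51 ± 0.06). Hepatocyte transcription factors and markers fell in 7 and rose in 1 of 15 cases (8 and 1 adjusted over the list alone; camera adjusted p = 4.9e-04), ONECUT1 and FOXA1 (−0.67 ± 0.07) among the falls. The stress list had 8 rises and 4 falls in 16 (9 and 4 adjusted over the list alone; camera adjusted p = 0.0043, adjusted p = 0.14 with an estimated correlation). Asparagine synthetase (ASNS, 1.74 ± 0.09) and DDIT3 (1.08 ± 0.10) rose, and SDF2L1 (−1.23 ± 0.14), CRELD2 (−0.85 ± 0.16) and XBP1 (−0.65 ± 0.08) fell. NF-kB and chemokine genes rose in 6 and fell in 1 of 12 cases (6 and 1 adjusted over the list alone; camera adjusted p = 0.0057, adjusted p = 0.075 with an estimated correlation), with CXCL8 (1.48 ± 0.12) higher and NFKB1 (−0.40 ± 0.08) lower.

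The remaining lists did not pass camera at 24 h of BRD8518 (adjusted p from 0.079 to 0.93). Among p53 targets PLK3 (1.87 ± 0.08) and GDF15 (1.53 ± 0.10) were 2 of 4 rises and BAX (−0.87 ± 0.13) and SESN1 (−0.82 ± 0.13) the 2 falls in 11 (4 and 2 adjusted over the list alone). The list had a median of −0.02, a mean of 0.21 and an upward test direction. Interferon-stimulated genes had 3 rises and 3 falls in 13 (3 and 3 adjusted over the list alone), with USP18 at −1.02 ± 0.08. Their median of 0.06, mean of −0.07 and downward test direction differed in sign. SRXN1 (1.07 ± 0.10), TXNRD1 (1.03 ± 0.07) and OSGIN1 (0.59 ± 0.12) were higher and HMOX1 (−1.10 ± 0.08) lower among 7 NRF2 targets (3 rises and 1 fall, 3 and 1 adjusted over the list alone). Hypoxia targets held 3 rises and 5 falls in 11 (3 and 7 adjusted over the list alone), with NDRG1 (1.01 ± 0.10) higher and BNIP3 (−0.75 ± 0.07) lower. The FGF19 co-receptor gene KLB (−1.53 ± 0.13) fell in the bile acid list (1 rise and 2 falls in 6, 1 and 3 adjusted over the list alone). The 1 rise in 8 heat shock genes (1 adjusted over the list alone; median −0.12) was HSPH1 (0.38 ± 0.11), which did not pass with the position term (0.34). Of the markers of other cell types, CD68 (1.19 ± 0.08) and the biliary keratin KRT19 (0.97 ± 0.10) were higher, 2 of 12 (2 adjusted over the list alone).

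OSM signals through gp130 and the OSM receptor to JAK kinases and STAT3, and at 1 h its strongest response was SOCS3, the feedback inhibitor of that pathway. SOCS3 rose 26.9-fold, from 5.48 ± 0.12 to 10.23 ± 0.09 (SD, n = 3 each; 4.75 ± 0.14, limma, Benjamini-Hochberg adjusted p = 3.8e-16). LBP, the lipopolysaccharide-binding protein of plasma, rose 13.3-fold (3.73 ± 0.13), JUNB 10.9-fold (3.44 ± 0.12), EGR1 10.8-fold (3.43 ± 0.13) and the interferon-regulatory factor IRF1 7.7-fold (2.94 ± 0.11). CSRNP1 (2.36 ± 0.13), the kinase gene RIPK4 (2.29 ± 0.11), the plasma glycoprotein LRG1 (2.27 ± 0.09), KLF6 (2.07 ± 0.09) and the precursor probe set MIR146B (2.72 ± 0.18) followed. TRIB1 was 3.21-fold higher (1.68 ± 0.08, limma, Benjamini-Hochberg adjusted p = 3.1e-12), and TRIB3 (0.20 ± 0.09), TRIB2 (0.08 ± 0.11), APOB (−0.04 ± 0.07) and MTTP (−0.11 ± 0.18) did not pass. The thioredoxin-binding TXNIP fell by 1.32 on the log2 scale (SE 0.14) and SMAD7, an inhibitor of TGF-beta signalling, by 0.99 (SE 0.11). ARHGEF35 (−1.97 ± 0.34), the pseudogene probe sets RPL23AP32 (−1.79 ± 0.20) and FRG1HP (−1.31 ± 0.21), and the precursor probe sets MIR3646 (−1.59 ± 0.29), MIR608 (−1.14 ± 0.16) and MIR4499 (−1.15 ± 0.18) fell. These precursors lie within HNF4A, SEMA4G and CRYL1, and the OSM means of MIR3646 (1.98) and MIR4499 (1.81) and the DMSO mean of MIR146B (3.12) are low for this array.

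At 1 h of OSM 423 genes passed, 302 higher and 121 lower, with 68 at least 2-fold higher and 9 at least 2-fold lower. The count was 274 without DMSO replicate 3, 806 without the 6 h DMSO array that lay apart (475 higher and 331 lower) and 1125 with array weights. The precursor probe sets MIR548L (−1.38 ± 0.35), within MRE11, and MIR4659A (−1.20 ± 0.28), within AGPAT5, also fell. The MIR548L call was lost without any 1 of the 6 arrays except OSM replicate 2, where it fell by 1.00 to 1.49 on the log2 scale, in a fit of these arrays alone and with the position term. MIR4659A did not pass without DMSO replicate 1 (−1.20), DMSO replicate 3 (−1.16) or OSM replicate 3 (−1.05), or with the mean of its probe sets (−0.48).

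JAK-STAT feedback and STAT3 targets rose at 1 h of OSM in 16 of 21 cases with 0 falls (17 adjusted over the list alone; median 0.81, camera, Benjamini-Hochberg adjusted p = 3.6e-46), SOCS3, JUNB, IRF1 and FOS (1.85 ± 0.16) leading. Positive acute phase proteins rose in 11 of 17 cases (13 adjusted over the list alone; median 0.62, camera adjusted p = 5.4e-35), with LBP, HPX (1.77 ± 0.10), HP (1.58 ± 0.10) and HAMP (1.49 ± 0.19). MAPK immediate-early and feedback genes rose in 20 of 29 cases (23 rises and 1 fall adjusted over the list alone; median 0.68, camera adjusted p = 1.1e-58). NF-kB and chemokine genes rose in 4 of 12 cases (5 adjusted over the list alone; camera adjusted p = 6.0e-11), with BCL3 (1.20 ± 0.08), ICAM1 (1.12 ± 0.07), CCL20 (0.98 ± 0.10) and NFKB2 (0.65 ± 0.14), the last not called without DMSO replicate 2 (0.61) or OSM replicate 2 (0.59). IRF1 and IRF9 (1.23 ± 0.08) were among 5 rises in 13 interferon-stimulated genes (5 adjusted over the list alone; camera adjusted p = 1.0e-05). Of 11 p53 targets PLK3 (1.07 ± 0.08) and GDF15 (0.81 ± 0.10) rose (3 adjusted over the list alone; camera adjusted p = 0.0014).

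Smaller shifts of lists at 1 h of OSM passed camera and were lost with an estimated correlation. SRF/MRTF and YAP targets had 3 rises in 12 (4 rises and 1 fall adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 5.2e-04, adjusted p = 0.095 with an estimated correlation), the small GTPase gene RHOB (1.04 ± 0.09), ANKRD1 (0.77 ± 0.09) and SRF (0.34 ± 0.07). SRF was not called without DMSO replicate 1 (0.29) or OSM replicate 1 (0.32), or in a fit of these arrays alone. The stress list had 3 rises and 1 fall in 16 (3 and 1 adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.19 with an estimated correlation), with ATF3 (1.38 ± 0.14) and XBP1 (0.93 ± 0.08). Heat shock genes had 2 rises in 8 (3 adjusted over the list alone; camera adjusted p = 0.02, adjusted p = 0.089 with an estimated correlation). They were BAG3 (0.40 ± 0.09), not called without DMSO replicate 3 (0.29) or OSM replicate 1 (0.38), and HSPA1A (0.28 ± 0.07), called only without DMSO replicate 3 among the fits with 1 of these 6 arrays left out (0.24 to 0.30 in the others). Mitosis (median −0.07, camera adjusted p = 0.015, adjusted p = 0.4 with an estimated correlation) and DNA replication (median −0.09, camera adjusted p = 0.0035, adjusted p = 0.12 with an estimated correlation) had 0 of 22 and 0 of 21 members past the threshold (0 and 0 adjusted over the list alone). BRD8518 had medians of −0.05 and −0.08 against the same DMSO arrays, so the shared controls cannot be told apart from an effect of OSM.

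Camera adjusted p values of the other 9 lists at 1 h of OSM ran from 0.051 to 0.65. The lipogenic THRSP (0.93 ± 0.18) and MID1IP1 (0.64 ± 0.12) rose among 19 fatty acid genes (2 adjusted over the list alone). PROX1 (0.84 ± 0.07) was the largest of 3 rises against 1 fall, FOXA2 (−0.34 ± 0.06), among 15 hepatocyte genes (3 and 1 adjusted over the list alone). HMOX1 (0.65 ± 0.08) rose among NRF2 targets, and ADM (1.19 ± 0.12) and VEGFA (0.58 ± 0.09) among hypoxia targets. The monocyte-associated CD14 (0.78 ± 0.14) was 1 of 12 markers of other cell types that rose (1 adjusted over the list alone). Of the 16 AhR and PXR/CAR targets fixed, TIPARP was the 1 measured, and it rose by 0.46 ± 0.07. Cholesterol synthesis genes had 0 of 17 past the threshold (0 adjusted over the list alone; median 0.08).

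By 24 h of OSM, LBP was 51.8-fold above DMSO, at 10.40 ± 0.15 against 4.70 ± 0.17 (SD, n = 3 each; 5.70 ± 0.13, limma, Benjamini-Hochberg adjusted p = 3.5e-18). LY96, which encodes the TLR4 partner MD-2, rose 15-fold (3.91 ± 0.21), SOCS3 11.1-fold (3.47 ± 0.14), FLRT3 7.19-fold (2.85 ± 0.15) and the hyaluronan receptor gene LYVE1 6.48-fold (2.70 ± 0.16). JUNB (2.24 ± 0.12), IGFBP1 (2.21 ± 0.14), the metalloproteinase inhibitor TIMP1 (2.11 ± 0.16), MAB21L3 (2.17 ± 0.12) and RGCC (2.09 ± 0.14) followed. The glutathione transferases GSTA2 (−2.73 ± 0.34) and GSTA1 (−1.87 ± 0.16), near-identical copies that probe sets may not separate, fell. So did MIXL1 (−2.43 ± 0.10), the antimicrobial peptide gene LEAP2 (−2.00 ± 0.11), the Wnt antagonist DKK4 (−1.98 ± 0.15), the prolactin receptor PRLR (−1.90 ± 0.15), TMT1A (−1.84 ± 0.14), HMGCS1 (−1.71 ± 0.08), PDZK1 (−1.65 ± 0.17) and the cholesterol esterifying SOAT2 (−1.61 ± 0.09). TRIB1 was 1.48-fold higher (0.57 ± 0.08, limma, Benjamini-Hochberg adjusted p = 4.1e-05) and MTTP fell 2.42-fold (−1.28 ± 0.18), to 7.69 ± 0.17. TRIB3 (−0.12 ± 0.09), TRIB2 (−0.05 ± 0.11) and APOB (−0.04 ± 0.07) did not pass. In total 1526 genes passed, 685 higher and 841 lower, with 68 at least 2-fold higher and 46 at least 2-fold lower. The count was 2535 without the 6 h DMSO array that lay apart and 3068 with array weights.

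Positive acute phase proteins rose at 24 h of OSM in 12 of 17 cases with 0 falls (15 adjusted over the list alone; median 0.63, camera, Benjamini-Hochberg adjusted p = 1.5e-25), with HP (1.81 ± 0.10), the fibrinogen chain FGB (1.51 ± 0.10) and CP (1.22 ± 0.11). Negative acute phase proteins fell in 4 of 9 cases (6 adjusted over the list alone; median −0.35, camera adjusted p = 2.0e-04), namely APOA1 (−0.79 ± 0.15), APOM (−0.54 ± 0.10), TTR (−0.46 ± 0.07) and TF (−0.35 ± 0.06). JAK-STAT feedback and STAT3 targets rose in 14 and fell in 1 of 21 cases (15 and 1 adjusted over the list alone; camera adjusted p = 8.2e-16), with SOCS1 (1.41 ± 0.13) higher and the LIF receptor gene LIFR (−1.06 ± 0.12) lower. MAPK immediate-early and feedback genes rose in 10 and fell in 2 of 29 cases (11 and 2 adjusted over the list alone; camera adjusted p = 1.9e-07), with EGR1 at 1.38 ± 0.13 and SPRY2 at −0.40 ± 0.09. ICAM1 (0.93 ± 0.07), BCL3 (0.63 ± 0.08) and CCL20 (0.62 ± 0.10) were the 3 rises among 12 NF-kB and chemokine genes (3 adjusted over the list alone; camera adjusted p = 4.3e-04). Interferon-stimulated genes rose in 5 and fell in 1 of 13 cases (5 and 2 adjusted over the list alone; camera adjusted p = 0.0072, adjusted p = 0.057 with an estimated correlation). IFITM1 (1.90 ± 0.14) and its close copy IFITM2 (1.66 ± 0.10) rose and USP18 (−0.87 ± 0.08) fell.

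Metabolic lists fell at 24 h of OSM. Of 17 cholesterol synthesis and uptake genes 15 fell and 0 rose (15 adjusted over the list alone; median −0.84, camera, Benjamini-Hochberg adjusted p = 7.8e-24), with HMGCS1, ACAT2 (−1.27 ± 0.08), MVK (−1.13 ± 0.10) and HSD17B7 (−1.11 ± 0.24). Fatty acid and triglyceride synthesis genes fell in 11 and rose in 1 of 19 cases (13 and 2 adjusted over the list alone; camera adjusted p = 1.9e-08), with PNPLA3 (−1.32 ± 0.09) and DGAT1 (−1.04 ± 0.07) lower and LPIN2 (0.66 ± 0.09) higher. Lipoprotein genes fell in 6 and rose in 2 of 19 cases (8 and 2 adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.054 with an estimated correlation), with APOC3 (−1.31 ± 0.13), LCAT (−0.82 ± 0.10) and MTTP among the falls and VLDLR (0.65 ± 0.10) among the rises. KLB (−1.04 ± 0.13) and BAAT (−0.88 ± 0.12) were the 2 falls among 6 bile acid genes (1 rise and 3 falls adjusted over the list alone; camera adjusted p = 0.018). Hepatocyte transcription factors and markers fell in 7 of 15 cases (1 rise and 8 falls adjusted over the list alone; camera adjusted p = 1.9e-04), with ONECUT1 at −1.34 ± 0.14 and FOXA1 at −0.45 ± 0.07. DNA replication genes fell in 18 of 21 cases (20 adjusted over the list alone; median −0.53, camera adjusted p = 1.5e-23), with UHRF1 (−0.91 ± 0.11) and MCM2 (−0.77 ± 0.10) as examples. Mitosis genes fell in 15 of 22 cases (15 adjusted over the list alone; median −0.37, camera adjusted p = 1.8e-13), with KIF11 (−0.57 ± 0.10) and CDK1 (−0.55 ± 0.12). The other 7 lists had camera adjusted p values from 0.062 to 0.46, and NRF2 targets, with 0 rises and 2 falls in 7 (0 and 2 adjusted over the list alone), had a median of 0.01 beside a mean of −0.07 and a downward test direction. Of the markers of other cell types, CD14 (0.74 ± 0.14), CD68 (0.34 ± 0.08) and SOX9 (0.21 ± 0.06) were higher and PECAM1 (−0.43 ± 0.10) was lower, 4 of 12 (3 and 1 adjusted over the list alone). SOX9 did not pass without DMSO replicate 3 (0.21), OSM replicate 2 (0.21) or OSM replicate 3 (0.22), with the position term, or in a fit of these arrays alone.

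**Figure D3:**
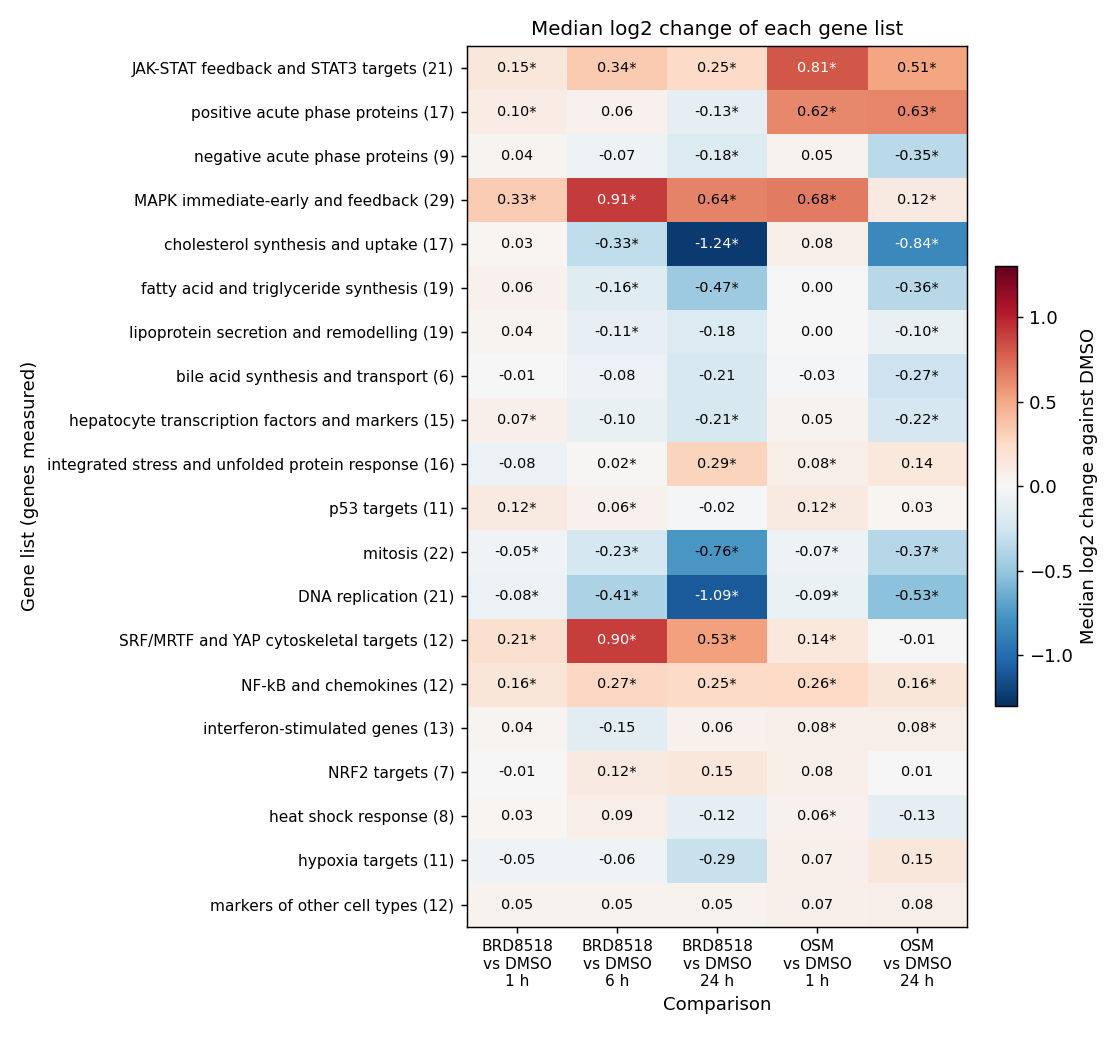
Median log2 change against time-matched DMSO (colour and printed value) of the 20 gene lists tested (vertical axis, with the number of genes measured) in the 5 comparisons (horizontal axis), where an asterisk marks a camera adjusted p under 0.05. Cholesterol synthesis and uptake genes were lowest at 24 h, with medians of −1.24 for BRD8518 and −0.84 for OSM, and JAK-STAT feedback and STAT3 targets were highest at 1 h of OSM (0.81).

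Set against each other at 1 h, BRD8518 and OSM differed in 349 genes, 126 higher and 223 lower with BRD8518. SOCS3 was 24.3-fold lower (−4.60 ± 0.14, limma, Benjamini-Hochberg adjusted p = 7.4e-16), LBP 12.2-fold lower (−3.60 ± 0.13), IRF1 6.92-fold lower (−2.79 ± 0.11), MIR146B 6.65-fold lower (−2.73 ± 0.18) and JUNB 5.11-fold lower (−2.35 ± 0.12) with BRD8518 than with OSM. TRIB1 was 2.78-fold lower (−1.48 ± 0.08, limma, Benjamini-Hochberg adjusted p = 4.1e-11), and TRIB3 (−0.32 ± 0.09) did not pass. ARRDC3 was higher with BRD8518 (1.63 ± 0.13), as were ARHGEF35 (1.69 ± 0.34) and the precursor probe sets MIR548L (1.98 ± 0.35), MIR554 (1.81 ± 0.15) and MIR3646 (1.41 ± 0.29). With the position letter as a term, which rests on BRD8518 replicate 1 alone, the changes were 1.85 for ARHGEF35 and 1.14 for MIR3646. The count was 224 without OSM replicate 3, 716 without the 6 h DMSO array that lay apart, and 934 with array weights (473 higher and 461 lower).

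All 8 lists that differed at 1 h were lower with BRD8518 than with OSM. JAK-STAT feedback and STAT3 targets were lower in 14 and higher in 2 of 21 cases (16 and 2 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 1.1e-32), with CISH at −1.62 ± 0.09 and BCL6 at 0.66 ± 0.08. Lower too were 9 of 17 positive acute phase proteins (9 adjusted over the list alone; camera adjusted p = 6.6e-29). MAPK genes were lower in 13 of 29 with 1 higher (18 and 2 adjusted over the list alone; camera adjusted p = 2.2e-23), KLF10 (−1.63 ± 0.09) and IER3 (−1.03 ± 0.08) among the lower. Interferon-stimulated genes were lower in 4 of 13 (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.5e-05) and NF-kB and chemokine genes in 4 of 12 (5 lower and 2 higher adjusted over the list alone; camera adjusted p = 4.1e-04). Hypoxia targets were lower in 3 of 11 (4 adjusted over the list alone; camera adjusted p = 7.2e-04). In the stress list 2 of 16 were lower (4 adjusted over the list alone; camera adjusted p = 8.7e-05, adjusted p = 0.067 with an estimated correlation), ATF3 at −0.87 ± 0.14 and XBP1 at −0.78 ± 0.08. With the position letter as a term, which rests on BRD8518 replicate 1 alone, ATF3 was at −0.78. HMOX1 (−0.67 ± 0.08) was the 1 lower of 7 NRF2 targets (1 adjusted over the list alone; camera adjusted p = 0.02, adjusted p = 0.12 with an estimated correlation).

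At 24 h the 2 treatments differed in 3458 genes, 1623 higher and 1835 lower with BRD8518, or 1891 and 1540 with arrays centred. LAIR2, low for this array with OSM (2.91), was 21.1-fold higher with BRD8518 (4.40 ± 0.23), DUSP5 14.1-fold (3.82 ± 0.13), AXL 13.5-fold (3.76 ± 0.10, limma, Benjamini-Hochberg adjusted p = 1.8e-17), IL11 9.5-fold (3.25 ± 0.15) and ANKRD1 7.24-fold (2.86 ± 0.09). LBP was 44.6-fold lower (−5.48 ± 0.13), HPR 12.4-fold (−3.63 ± 0.14), SOCS3 9.4-fold (−3.23 ± 0.14), SOCS1 8.26-fold (−3.05 ± 0.13) and the receptor gene GPR119 7.52-fold (−2.91 ± 0.18). TRIB3 was 2.57-fold higher (1.36 ± 0.09) and TRIB1 1.56-fold higher (0.64 ± 0.08, limma, Benjamini-Hochberg adjusted p = 3.4e-06) with BRD8518. For MTTP, lower than DMSO with both treatments, the difference between them was 0.22 (95% confidence interval −0.16 to 0.61) and did not pass. With array weights 5286 genes passed.

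Positive acute phase proteins were lower with BRD8518 than with OSM at 24 h in 13 of 17 cases (13 adjusted over the list alone; median −0.88, camera, Benjamini-Hochberg adjusted p = 4.2e-17), with HP at −2.61 ± 0.10 and CP at −2.34 ± 0.11. DNA replication genes were lower in 18 of 21 (20 adjusted over the list alone; camera adjusted p = 1.1e-14), FEN1 (−1.21 ± 0.10) among them. Mitosis genes were lower in 17 of 22 (19 adjusted over the list alone; camera adjusted p = 3.3e-10, adjusted p = 0.052 with an estimated correlation). Cholesterol genes were lower in 10 of 17 with 1 higher (12 and 1 adjusted over the list alone; median −0.38, camera adjusted p = 1.9e-05). Hypoxia targets were lower in 7 and higher in 2 of 11 (7 and 2 adjusted over the list alone; camera adjusted p = 0.011). Interferon-stimulated genes were lower in 5 of 13 (5 adjusted over the list alone; camera adjusted p = 0.0035, adjusted p = 0.052 with an estimated correlation). SRF/MRTF and YAP targets were higher in 10 of 12 (11 adjusted over the list alone; camera adjusted p = 1.1e-10), with TAGLN at 1.97 ± 0.11. MAPK genes were higher in 14 of 29 with 2 lower (14 and 2 adjusted over the list alone; camera adjusted p = 6.4e-09). The stress list had 9 higher and 4 lower of 16 (9 and 4 adjusted over the list alone; camera adjusted p = 0.0035, adjusted p = 0.16 with an estimated correlation). Among NRF2 targets there were 3 higher and 1 lower of 7 (3 and 1 adjusted over the list alone; camera adjusted p = 0.03, adjusted p = 0.16 with an estimated correlation). JAK-STAT feedback and STAT3 targets went both ways, with 7 higher and 11 lower of 21 (7 and 11 adjusted over the list alone; camera adjusted p = 0.39), IL6R (1.37 ± 0.09) and LIFR (1.20 ± 0.12) higher and the OSM receptor gene OSMR (−1.27 ± 0.07) lower.

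The change of the BRD8518 effect with time was tested on differences of effects, each against its own DMSO arrays. From 1 h to 6 h the TRIB1 effect grew by 1.19 ± 0.12 and the TRIB3 effect by 0.91 ± 0.13 (limma, Benjamini-Hochberg adjusted p = 1.6e-06 and 1.4e-04). RGCC (2.56 ± 0.20), KRTAP2-3 (2.51 ± 0.32), LINC-PINT (2.06 ± 0.24), PLK3 (2.03 ± 0.12) and ANKRD1 (1.95 ± 0.14) gained most, and ZNF563 (−1.73 ± 0.32), FAM200C (−1.65 ± 0.29), the sterol enzyme HSD17B7 (−1.53 ± 0.35), KBTBD7 (−1.35 ± 0.28) and KAT14 (−1.35 ± 0.16) lost most. From 1 h to 6 h 895 genes differed, 313 upward and 582 downward, or 494 and 332 with arrays centred. The count was 558 without BRD8518 6 h replicate 1, 498 without BRD8518 6 h replicate 2 and 1898 without DMSO 6 h replicate 2. It was 1989 with array weights and 327 in a fit of these arrays alone. HSD17B7 did not pass in that fit, and its change was −1.49 without BRD8518 6 h replicate 2. With the position term, which rests on BRD8518 1 h replicate 1 alone, it was −1.48, and that of KBTBD7 was −1.17.

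From 6 h to 24 h the TRIB1 effect did not differ by the test (−0.19 ± 0.12, limma, Benjamini-Hochberg adjusted p = 0.42), and the MTTP effect fell by 1.05 on the log2 scale (SE 0.27), or by 0.79 without DMSO 6 h replicate 2. LAIR2 (3.37 ± 0.33), TCP11L2 (2.70 ± 0.16), AXL (2.57 ± 0.14), TMEM156 (2.54 ± 0.18) and AQP7P3 (2.53 ± 0.24) gained most, and MAP2K6 (−2.58 ± 0.25), DKK4 (−2.36 ± 0.21), TMT1A (−2.30 ± 0.20), CHST9 (−2.22 ± 0.33) and ADH6 (−2.21 ± 0.36) lost most. The TRIB3 effect was 0.45 ± 0.13 larger at 24 h. Its call was lost without BRD8518 24 h replicate 2 (0.42) or 3 (0.45), BRD8518 6 h replicate 1 (0.45) or 2 (0.45), or DMSO 24 h replicate 1 (0.39) or 2 (0.38), and in a fit of these arrays alone. MTTP did not pass without BRD8518 6 h replicate 1 (−1.02) or in that fit. In this interval 1649 genes differed, 887 upward and 762 downward, or 711 and 939 with arrays centred. The count was 1018 without BRD8518 6 h replicate 2, 2741 without DMSO 6 h replicate 2, 2866 with array weights and 875 in a fit of these arrays alone.

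Between 1 h and 24 h the BRD8518 effect differed in 2604 genes, 1077 upward and 1527 downward, with TRIB1 at 1.00 ± 0.12 and TRIB3 at 1.36 ± 0.13, while MTTP fell by 1.00 on the log2 scale (SE 0.26). LAIR2 (4.69 ± 0.32), RGCC (3.83 ± 0.20), TMC7 (3.55 ± 0.20), AQP7P3 (3.48 ± 0.23) and DUSP5 (3.40 ± 0.18) gained most, and MAP2K6 (−2.81 ± 0.24), HOXD1 (−2.68 ± 0.22), TMT1A (−2.48 ± 0.19), GPR119 (−2.34 ± 0.25) and EPO (−2.31 ± 0.16) lost most. That count was 4012 with array weights. The OSM effect went the other way for TRIB1, which was 1.11 lower on the log2 scale at 24 h than at 1 h (−1.11 ± 0.12, limma, Benjamini-Hochberg adjusted p = 1.8e-06). SOCS3 (−1.28 ± 0.19) and MTTP (−1.17 ± 0.26) lost too. MIXL1 (−3.24 ± 0.15), GSTA2 (−3.02 ± 0.48), IRF1 (−2.55 ± 0.15), LEAP2 (−2.15 ± 0.16) and CSRNP1 (−2.08 ± 0.18) lost most, and LY96 (2.97 ± 0.30), RPL23AP32 (2.25 ± 0.28), TXNIP (2.12 ± 0.19), LBP (1.96 ± 0.18) and LYVE1 (1.87 ± 0.22) gained most. For OSM 502 genes differed between the times, 189 upward and 313 downward, or 1100 without the 6 h DMSO array that lay apart, 1324 with array weights and 828 in a fit of these arrays alone.

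Lists shifted with time as well. For BRD8518 from 6 h to 24 h, 12 of 17 cholesterol genes (13 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 1.0e-17) and 18 of 21 DNA replication genes (18 adjusted over the list alone; camera adjusted p = 2.3e-21) had lower effects at 24 h. From 1 h to 6 h, SRF/MRTF and YAP targets gained in 8 of 12 cases (9 adjusted over the list alone; camera adjusted p = 1.2e-17) and MAPK genes in 14 of 29 (14 adjusted over the list alone; camera adjusted p = 9.8e-17). For OSM, MAPK genes lost between 1 h and 24 h in 16 of 29 cases (20 adjusted over the list alone; camera adjusted p = 2.5e-28) and JAK-STAT targets in 8 of 21 with 2 gains (10 and 3 adjusted over the list alone; camera adjusted p = 8.1e-07). Cholesterol genes lost in 12 of 17 cases (15 adjusted over the list alone; camera adjusted p = 2.5e-28). Effects on positive acute phase proteins gained in 3 and lost in 2 of 17 cases (7 and 3 adjusted over the list alone; camera adjusted p = 0.0071, adjusted p = 0.083 with an estimated correlation).

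Calls overlapped across times and treatments. Of the genes higher with BRD8518, 26 passed at 1 h, 6 h and 24 h, among them EGR1, JUN, JUNB, KLF6, DUSP1, DUSP5, DUSP6, SPRY4, IER3, MYC, ANKRD1, EDN1, GDF15, CXCL8 and CCL20. For BRD8518 at 6 h and 24 h, 575 genes were higher and 778 lower at both times, where independent lists would share 101 and 206, and 46 had opposite calls. For OSM at 1 h and 24 h, 157 were higher and 27 lower at both, against 13.9 and 6.84 for independent lists. BRD8518 and OSM at 24 h, which share their DMSO arrays, had 391 genes higher and 631 lower in common, 1022 in all, against 83 and 130 for independent lists, and 113 with opposite calls. Across genes, which are not independent replicates, the changes correlated at r = 0.5, the value that shared controls alone gave in simulation (0.5), but their covariance was 0.054 against 0.0087 simulated, a difference of 0.045. At 1 h the 2 treatments shared 21 higher genes (0.67 for independent lists), 0 lower genes and 1 opposite call, with r = 0.43 (0.5 simulated) and a covariance of 0.012 against 0.0088 simulated. Control groups of 3 cannot be split with at least 2 arrays on each side, so part of each excess may come from the shared controls. BRD8518 at 6 h and OSM at 1 h, which share no arrays, had 141 higher and 62 lower genes in common (17 and 10.7 for independent lists) and 18 with opposite calls. Without the 6 h DMSO array that lay apart, BRD8518 and OSM shared 39 genes at 1 h and 1608 at 24 h, and with array weights 45 and 1878.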

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

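Of the tests in this part, the comparisons of DMSO 6 h replicate 2 with treatment effects, with markers of other cell types and with signal level were written after the array had been seen to stand apart, and before their own results were seen. Within groups, arrays correlated at r from 0.973 to 0.9969 across genes, and the lowest value without this array was 0.9948.

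In the 6 h DMSO group of 4, the only group given a Dixon test here, 13 of 88 named genes had 1 array far from the others, where 4.4 would be found by chance (about 1 in 20). In 12 of them the array was DMSO 6 h replicate 2, with gap ratios of 0.974 for CDC6, 0.903 for RBBP6, 0.901 for TAT, 0.884 for MTTP (7.96 against 8.95 to 9.08), 0.874 for SDF2L1, 0.873 for PIM1 and 0.862 for IRF1. The others were 0.86 for HMOX1, 0.848 for MLXIPL, 0.844 for IRAK2, 0.836 for JUNB and 0.832 for APOA1. For TRIB1 it was DMSO 6 h replicate 1, at 8.96 against 9.20 to 9.23 (0.893).

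DMSO 6 h replicate 2 spread more from its group than any other array, with a residual SD of 0.329. A BRD8518 or OSM array of 24 h under a DMSO label is argued against, since its deviation correlated at r = 0.066 and 0.17 with these effects. For the effects at 1 h the values were 0.15 and 0.25. They cannot decide there, since only 38 and 423 of 14884 genes changed. No such correlation was computed for BRD8518 at 6 h. EGR1, looked at after its values were seen, argues against a treated array of 1 h or 6 h. It was 8.49 in this array and 7.95 to 8.21 in the other 6 h DMSO arrays. With BRD8518 it was 11.23 to 11.58 at 1 h and 11.53 to 11.54 at 6 h. With OSM at 1 h it was 11.80 to 11.85. TRIB1 (9.23) lay below BRD8518 at 6 h (10.47 to 10.61) and OSM at 1 h (10.69 to 10.89). It lay near BRD8518 at 1 h (9.30 to 9.35). A shift by signal level alone is argued against too, since the SD was 0.42 after a level trend was removed and at most 0.2 in the other 23 arrays. RNA of another cell type stays open, although the markers of other cell types deviated by a median of 0.01 (matched lists −0.21 to 0.23), because the 12 measured went both ways (−0.42 to 0.40) and such a median decides nothing. Handling of the RNA or of the array may be a cause and was not tested. No biological explanation was tested.

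Effects that differed between times were found by a test of the difference (limma, Benjamini-Hochberg). The BRD8518 effect differed in 895 genes between 1 h and 6 h, 1649 between 6 h and 24 h and 2604 between 1 h and 24 h, and the OSM effect in 502 between 1 h and 24 h. Among panel genes, TRIB1 differed by 1.19 from 1 h to 6 h and by 1.00 from 1 h to 24 h with BRD8518, and by −1.11 from 1 h to 24 h with OSM. TRIB3 differed by 0.91 (1 h to 6 h), 0.45 (6 h to 24 h) and 1.36 (1 h to 24 h) with BRD8518. MTTP differed by −1.05 (6 h to 24 h; −0.79 without DMSO 6 h replicate 2) with BRD8518 and by −1.17 with OSM, and SOCS3 by −1.28 with OSM. From 1 h to 24 h the BRD8518 effect on MTTP fell by 1.00 on the log2 scale.

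Splitting the arrays of both groups in other ways gave 0 genes at most in each of 9 other splits, against 38 and 4122 for BRD8518 at 1 h and 24 h, 423 and 1526 for OSM at 1 h and 24 h, and 349 and 3458 between the treatments at 1 h and 24 h. In each case 1 of 10 splits, the real one, reached the count, and 10 splits are too few for a share under 0.05. For the effect between 1 h and 24 h, 8 of 100 splits reached 2604 genes for BRD8518 (highest other 2981) and 6 of 100 reached 502 for OSM (highest other 715). All of these kept the 24 h arrays grouped as labelled or mirrored and so held the 24 h difference itself, which leaves open whether chance can be excluded. The highest count with the 24 h arrays mixed was 3 for BRD8518 and 174 for OSM.

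Probe sets without a gene name, outside the comparisons of the report, also gave a signal. With the same limma fit over the 37519 unnamed here, 27, 1780 and 3145 passed a Benjamini-Hochberg adjusted p of 0.05 for BRD8518 at 1 h, 6 h and 24 h, and 395 and 869 for OSM at 1 h and 24 h.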

How the results depend on the processing

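Of 587 named gene results, 547 were past the threshold, 114 of those lost their call under at least 1 alternative, and 0 changed sign. Numbers of genes moved by more than 1.5 times in these cases. With array weights they were 81, 3466, 1125 and 3068 for BRD8518 at 1 h and 6 h and OSM at 1 h and 24 h, 934 and 5286 between the treatments at 1 h and 24 h. They were 1989, 2866 and 4012 for the BRD8518 effect from 1 h to 6 h, 6 h to 24 h and 1 h to 24 h, and 1324 for the OSM effect between times. Shared calls were then 45 at 1 h and 1878 at 24 h. Without DMSO 6 h replicate 2, a fit added after that array was seen to stand apart, they were 76, 3345, 806 and 2535 for the same 4 comparisons with DMSO, and 716 between the treatments at 1 h. They were 1898 and 2741 for the BRD8518 effect from 1 h to 6 h and from 6 h to 24 h, and 1100 for the OSM effect, with 39 and 1608 shared calls. Both settings give that array little or no part in the pooled spread, its weight being 0.0635. Fitted on the compared groups alone, BRD8518 at 6 h had 452 genes, the BRD8518 effect 327 from 1 h to 6 h and 875 from 6 h to 24 h, and the OSM effect 828. For those with 6 h arrays the noisier array then sets more of the spread, and for OSM it is absent. With the position letter as a fixed term BRD8518 at 1 h had 15 genes, the treatments at 1 h differed in 183, and the BRD8518 effect in 401 from 1 h to 6 h and 1605 from 1 h to 24 h. The cause was not tested. As a random block the letter had a consensus correlation of −0.085. Lists past the threshold at 1 h of OSM numbered 6 with an estimated correlation, which by its construction widens the test for lists whose genes vary together.

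The ranges here cover only arrays of the compared groups, and outside them the fits without DMSO 6 h replicate 2 gave more genes. With 1 such array left out, numbers of genes ran from 25 to 38 for BRD8518 at 1 h, 1208 to 3345 at 6 h and 3539 to 3704 at 24 h, and from 274 to 362 for OSM at 1 h and 1107 to 1222 at 24 h. They ran from 224 to 296 and 2741 to 3087 between the treatments at 1 h and 24 h. They ran from 498 to 1898, 1018 to 2741 and 2196 to 2416 for the BRD8518 effect from 1 h to 6 h, 6 h to 24 h and 1 h to 24 h, and from 384 to 446 for the OSM effect. Shared calls ran from 16 to 23 at 1 h and 760 to 956 at 24 h. Lists ran from 6 to 9, 11 to 13 and 12 to 13 for BRD8518 at the 3 times and 9 to 13 and 13 to 14 for OSM. Fewer arrays give a weaker test by construction. With 1 of its arrays left out BRD8518 at 6 h keeps 1, which is assumed to vary like the other groups. No paired analysis was possible because replicate numbers follow the order of the samples and the labels pair no arrays. With arrays centred the balance of higher and lower calls turned for BRD8518 at 6 h (836 and 1319 against 1309 and 943), for its effect from 1 h to 6 h (313 and 582 against 494 and 332) and from 6 h to 24 h (887 and 762 against 711 and 939), and between the treatments at 24 h (1623 and 1835 against 1891 and 1540). The last 2 balances also turned in some other fits. Signal over background limits dim probe sets, for which no detection calls were used.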

Other observations

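Of the tests in this part, the difference between 24 h and 6 h for zinc-finger genes and the cholesterol comparison with the 1 h DMSO arrays were chosen only after the results were seen. The symbol families below were chosen after their values were seen, among 179 families of at least 10 genes. Fisher tests, here and below, treat genes as independent. Related genes read on the same arrays may vary together, so these p-values may be too small. At 24 h of BRD8518, 23 of 52 genes with MRPL symbols fell, most of them for proteins of the large mitochondrial ribosomal subunit and 1 the antisense RNA MRPL23-AS1 (−0.50 ± 0.11), 44.2% against 15.6% of all genes, with a median of −0.23 (Fisher, Benjamini-Hochberg adjusted p = 3.1e-04), among them MRPL11 (−0.93 ± 0.09), MRPL43 (−0.64 ± 0.08) and MRPL48 (−0.63 ± 0.12). With OSM at 24 h 1 of 52 fell, where 5.65% of all genes were lower, and the difference between the treatments was not tested. Intraflagellar transport genes (IFT) fell with BRD8518 at 24 h in 9 of 17 cases (52.9% against 15.6% of all genes), with a median of −0.42 (Fisher, Benjamini-Hochberg adjusted p = 0.024), such as IFT81 (−0.91 ± 0.12) and IFT172 (−0.51 ± 0.09). Lower too were IFT70A (−1.91 ± 0.27) and IFT70B (−1.22 ± 0.20), near-identical copies whose probe sets may read each other. With OSM at 24 h, 10 of 40 kinesin genes (KIF) fell (25% against 5.65% of all genes; Fisher, adjusted p = 0.0067), including KIF15 (−0.59 ± 0.12) and KIF18B (−0.56 ± 0.13). KIF11, KIF20A and KIF23 were among them and also belong to the mitosis list. Of genes for centrosomal proteins (CEP), 10 of 38 fell (Fisher, adjusted p = 0.0063), including CEP126 (−0.61 ± 0.16), CEP152 (−0.54 ± 0.13) and CEP192 (−0.47 ± 0.09).

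Zinc-finger genes with ZNF symbols were common among the falls at 6 h of BRD8518, where 115 of 491 fell (23.4% against 8.86% of all genes; median −0.18, and −0.11 with arrays centred) and 11 rose. The array that lay apart is argued against as the source, since 36.9% were lower without it, against 14.7% of all genes. Low signal is argued against as well, since lists matched on level had 8.15% to 13.4% lower. The effect was 0.10 closer to 0 at 24 h than at 6 h in the median (matched lists −0.01 to 0.04; median at 24 h −0.08). At 24 h 98 of 491 were lower (20% against 15.6% of all genes; Fisher, Benjamini-Hochberg adjusted p = 0.11). The family was picked for its falls at 6 h, and the lists were matched on level alone. Part of such a shift can follow from that choice, so whether the fall passes stays open. With OSM 22 of 491 were lower at 1 h (4.48% against 0.813%; adjusted p = 2.1e-08) and 21 at 24 h (4.28% against 5.65%; adjusted p = 1), with BRD8518 0 at 1 h, and no biological explanation was tested.

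Cholesterol synthesis and uptake genes were lower at 24 h with both treatments, with medians of −1.24 for BRD8518 and −0.84 for OSM. A high level in the shared 24 h DMSO arrays is argued against, since the medians were −1.27 and −0.76 against the 1 h DMSO arrays. A fall of all bright probe sets is argued against too, since matched lists had medians of −0.24 to 0.15 for BRD8518 and −0.13 to 0.08 for OSM. A shared response of sterol-regulated genes may account for it and stays open. No biological explanation was tested.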
